A study of Rattus norvegicus with 29 samples.

How the data were processed

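RNA of blood mononuclear cells from 29 male Wistar rats was measured on 29 Agilent rat whole-genome oligonucleotide arrays of 2 colours, with 1 rat per array. Per the labels, the cells were isolated by Ficoll gradient from saphenous vein blood, and their RNA was amplified linearly, labelled with Cy5 and hybridised beside a Cy3-labelled reference pooled from the samples. Every array carried the rat's own RNA in Cy5, so no dyes were swapped. A dye effect shared by all arrays cancels in each comparison of groups. The groups were control fed (4 rats) and control fasted, control refed, cafeteria fed, cafeteria fasted and cafeteria refed (5 rats each). Per the labels, the submitters left out 1 control sample for low RNA.

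Per the file headers, the authors' scanner files hold the mean intensity of each spot and the median intensity of its local background in both colours, made with Agilent Feature Extraction 9.5.1.1, with probe positions on the rn4 build. Per the headers these files also hold processed values, which the software had background-subtracted, detrended and dye-normalized. Flags mark spots well above background, saturated spots and outlier spots. The authors' deposited value table holds 1 column per array, which the labels call normalized Cy5 signal and which was found to be on a log2 scale. Against log2 of the scanner's Cy5 mean intensity, matched by spot number, its slope lay between 0.985 and 1.02 in the 29 columns. Its scale and direction are thus known, but how it was normalized between arrays is not given. The medians of its columns, in order of rat number, were 9.46, 9.51, 9.40 and 9.56 in control fed rats and 9.37, 9.47, 9.52, 9.49 and 9.49 in control fasted rats. They were 9.47, 9.51, 9.76, 9.68 and 9.57 in control refed rats and 9.49, 9.65, 9.59, 9.59 and 9.69 in cafeteria fed rats. They were 9.69, 9.53, 9.51, 9.46 and 9.49 in cafeteria fasted rats and 9.46, 9.64, 9.48, 9.56 and 9.59 in cafeteria refed rats.

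The values tested here were computed from the scanner files with R 4.3.3, limma 3.58.1 and the data.table package 1.17.8, and plots were drawn with matplotlib. Background was corrected with normexp and an offset of 50, and the log2 ratio of Cy5 over Cy3 was normalized within each array by loess, with control spots and spots marked as outliers at weight 0. Outlier spots were then left out (526 probe and array values), and replicate spots of a probe were averaged. Of 41012 probes, the 28242 whose Cy5 signal was well above background on at least 4 of the 29 arrays were kept. Each gene was represented by its brightest probe over all arrays, which gave 24279 genes, of which 11370 carried a gene symbol. Symbols came from the probe's accession, symbol or synonym in a reference gene table of the GRCr8 assembly, used for names only, and 19666 of the 41012 probes had a symbol. Names were set aside for 85 probes that lie on another chromosome than the named gene. Where other probes of a named gene went the other way, the text says so.

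The median Cy5 signal lay between 103.2 and 154.2 units. All arrays were scanned on 1 day, on 8 slides. The image extraction software was run in 2 runs, of 14 and 15 arrays, and the median Cy5 signal was 138.3 ± 7.10 units (SD, n = 14) in run 1 and 114.2 ± 7.69 units (SD, n = 15) in run 2. Run 1 held 1 of 5 cafeteria fasted, 4 of 5 cafeteria fed, 1 of 5 cafeteria refed, 4 of 5 control fasted, 2 of 4 control fed and 2 of 5 control refed arrays. The number of arrays limits the precision of every value.

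All 6 groups entered 1 limma fit (lmFit and eBayes), with no covariate. Fasted against fed, refed against fasted and refed against fed rats were compared within each diet, and cafeteria against control rats within each feeding condition and averaged over the 3 conditions. The difference between diets in the fasting response and in the refeeding response was tested as an interaction. P-values are 2-sided and were adjusted by Benjamini-Hochberg within each of the 12 comparisons, and a gene was called at an adjusted p under 0.05. The groups, comparisons, tests, gene lists, alternatives and the rule for naming genes were chosen before the data were examined.

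The rule named, per comparison, the 12 largest rises and the 12 largest falls among called genes with a symbol. Where fewer than 6 genes passed, it named all of them and the 5 with the smallest p, and for an interaction with no call the 3 with the smallest p. It added up to 4 passing members of each gene list that was called, or its 2 members with the largest change, and a fixed set of metabolic genes in every comparison, among them Slc27a2, Cpt1a, Pdk4, Srebf1, Srebf2, Fasn, Scd, Ppara, Ucp2, Txnip, Lepr and Insr. The text names part of these genes, and the results of some are not reported here. Pdk4 was not well above background on enough arrays to be tested.

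The 29 gene lists covered sterol synthesis and uptake, sterol efflux and LXR targets, fatty acid oxidation and PPAR targets, fatty acid and triglyceride synthesis, glycolysis and glucose transport, oxidative phosphorylation, glucocorticoid response, clock, FOXO and insulin-responsive genes, amino acid response, ER chaperones and unfolded protein response, heat shock, immediate early genes, interferon response, inflammatory cytokines and receptors, cell cycle, ribosomal proteins, ribosome biogenesis and nucleolus, proteasome and MHC class II presentation. They also covered markers of T cells, B cells, plasma cells, NK and cytotoxic cells, monocytes, neutrophils, eosinophils with basophils and mast cells, platelets with megakaryocytes, and erythroid cells. Each list was tested with limma's camera at a preset correlation of 0.01, with Benjamini-Hochberg adjustment over the lists within a comparison, and again with a correlation estimated per list. The preset correlation makes small p-values for lists whose genes vary together between rats, and all but 2 of the calls were lost with an estimated correlation.

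The fit was tested on simulated values of the 24279 genes and same arrays, with noise independent between genes and 200 changed by known folds. For fasting in control rats it recovered 82.1% of 1.5-fold and 98.5% of 2-fold changes, and for the diet in fed rats 86.6% and 95.5%. For refed against fed rats it recovered 86.6% and 95.5% in control rats, and 91% at both folds in cafeteria rats. A sterol list shifted 1.5-fold for fasting in control rats was called, and 0 other lists were. This cannot test lists whose genes vary together. In the 9 simulated comparisons, 8 to 13 unchanged genes were called.

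The alternatives tried were the software's processed signals, median centring in place of loess, the Cy5 channel alone with quantile normalization, the authors' deposited value table, no filter, a filter on all arrays, every probe tested, only the compared groups in the fit, array weights, slide as a block, the rat number as a block and each array left out in turn. After the data had been seen, the platelet marker mean was added as a covariate and the extraction run as a block. So were each run alone and the fatty acid oxidation list without Slc27a2. Chromosomes are those of the reference gene table.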

Results

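Gene expression was measured in blood mononuclear cells, the lymphocytes and monocytes of the blood, of 29 male rats at 6 months of age. Control rats ate standard chow, and cafeteria rats a fat-rich, high-calorie diet beside chow for 4 months, a model of diet-induced obesity. Rats of both diets were sampled while eating freely (fed), after 14 h without food (fasted) or after such a fast and 6 h of free access to food (refed). There were 4 control fed rats and 5 in each other group. The share of spots with Cy5 signal well above background was 59.1% to 66.7% in control fed, 60.55% to 64.68% in control fasted, 53.3% to 66.49% in control refed, 58.82% to 65.01% in cafeteria fed, 58.1% to 66.02% in cafeteria fasted and 59.84% to 66.24% in cafeteria refed arrays. Changes below are differences of group means of log2 ratios, each with its standard error after ±. For gene lists, the first adjusted p rests on a preset correlation between genes, and the adjusted p after "or" on an estimated correlation. Where leaving out 1 array moved the mean of a called list by over 1.5 times or ended the call, the array is named with that mean, or with the adjusted p. Where a block or covariate ended the call of a list, the new mean and adjusted p follow in parentheses. Counts under 4 alternative values are given in the order of processed signals, median centring, Cy5 alone and the authors' table.

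The mean of 23 platelet and megakaryocyte markers, such as Pf4 and Gp1bb, was highest in control fasted and lowest in control refed rats. This log2 ratio was 0.12 ± 0.54 (SD, n = 4) in control fed, 0.60 ± 0.11 (SD, n = 5) in control fasted and -0.80 ± 0.38 (SD, n = 5) in control refed rats. It was -0.14 ± 0.49 (SD, n = 5) in cafeteria fed, -0.028 ± 0.23 (SD, n = 5) in cafeteria fasted and -0.47 ± 0.73 (SD, n = 5) in cafeteria refed rats. The first principal component held 22.1% of the variance, and its correlation with the platelet marker mean had an absolute value of 0.948. Correlations between arrays lay between -0.282 and 0.605.

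**Figure D1:**
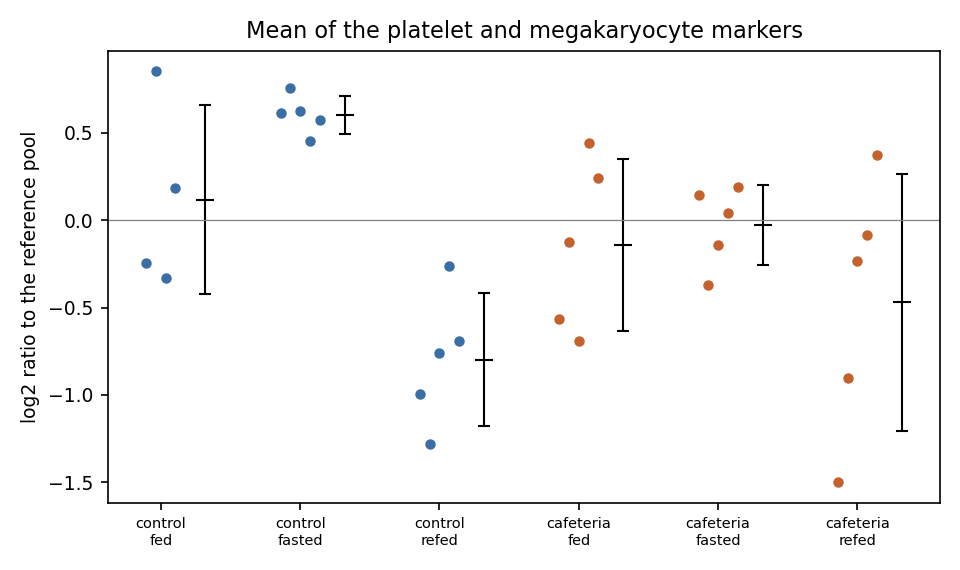
Mean log2 ratio of the 23 platelet and megakaryocyte markers in each array (points) by group, with the group mean and SD (bars). The group mean is -0.80 in control refed and 0.60 in control fasted rats.

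Comparing fasted with fed control rats asks whether blood mononuclear cells of normal-weight rats respond to a short fast. Bcl6 fell by 1.05 ± 0.16 (adjusted p = 0.00407), a 2.07-fold fall. Bcl6, on chromosome 11, encodes a transcriptional repressor best known from germinal centre B cells. Cebpd fell by 0.84 ± 0.17 (adjusted p = 0.0446), Tlr6 fell by 0.59 ± 0.11 (adjusted p = 0.0252) and Scd2 fell by 0.56 ± 0.12 (adjusted p = 0.0446), which encode a transcription factor of inflammation, a receptor for microbial lipopeptides and a fatty acid desaturase. Adam9 rose by 0.67 ± 0.13 (adjusted p = 0.0405), which encodes a membrane metalloprotease, and Tent5c rose by 0.58 ± 0.12 (adjusted p = 0.0446), which encodes a poly(A) polymerase.

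Of 24279 genes, 43 passed in this comparison, of which 18 rose and 25 fell. The alternative values gave 9, 2, 3 and 1 genes, slide as a block 16 (12 rises, 4 falls) and leaving out 1 array 6 to 81. The median change was 0.47 among the rises and -0.50 among the falls, and each called gene named here differed in that direction in all 5 fasted rats. Genes of sterol synthesis and uptake were lower as a list (mean -0.15, adjusted p = 4.36e-05, or 0.277). None of the 27 measured members passed over all genes and 7 fell when adjusted over the list alone. The change was -0.59 for Msmo1 (adjusted p = 0.0606), an enzyme of sterol synthesis. Genes of fatty acid and triglyceride synthesis were lower as a list (mean -0.053, adjusted p = 0.0292, or 0.277), and 1 of 24 fell over all genes against 4 that fell and 3 that rose adjusted over the list alone. ER chaperones and unfolded protein response genes, which help proteins fold, were higher (mean 0.23, adjusted p = 0.000153, or 0.82). None of 18 passed over all genes and 3 rose adjusted over the list alone, with 0.45 for Herpud1 (adjusted p = 0.104). Plasma cell markers had a mean of 0.24 (adjusted p = 0.111), with 1.954 in control fasted 2 and up to 0.2254 in the other fasted arrays. Ribosomal proteins were higher (mean 0.080, adjusted p = 0.0411, or 0.852), but were lower with processed signals (adjusted p = 0.0414).

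As a list, the platelet markers were higher (mean 0.49, adjusted p = 4.18e-05, or 0.82). Erythroid markers were higher (mean 0.21, adjusted p = 0.0414, or 0.82). Monocyte markers were lower (mean -0.11, adjusted p = 0.0292, or 0.82), and so were neutrophil markers (mean -0.23, adjusted p = 0.0292, or 0.82), with -0.92 for Retnlg (adjusted p = 0.406). None of the members of these 4 lists passed over all genes. Among metabolic genes named in advance, the change was 0.33 ± 0.081 for Cpt1a (adjusted p = 0.0701), -0.44 ± 0.12 for Srebf1 (adjusted p = 0.101), 0.61 ± 0.18 for Txnip (adjusted p = 0.146) and -0.25 ± 0.081 for Fasn (adjusted p = 0.193). With slide as a block, the call ended for fatty acid synthesis (-0.030, 0.17), ER chaperones (0.13, 0.129), monocyte markers (-0.070, 0.17) and neutrophil markers (-0.17, 0.269). With the platelet marker mean as a covariate, chosen after seeing the data, the call of erythroid markers ended (0.069, 0.577). With extraction run as a block, also chosen then, it ended for fatty acid synthesis (-0.042, 0.0682), ribosomal proteins (0.075, 0.0775), monocyte markers (-0.094, 0.0697) and neutrophil markers (-0.20, 0.0682). Single arrays moved fatty acid synthesis (control fed 1, -0.085), ER chaperones (control fasted 2, 0.062, adjusted p = 0.293), ribosomal proteins (control fed 4, -0.034, control fed 13, 0.14), monocytes (control fed 4, -0.070, control fasted 2, -0.054), platelets (control fed 4, 0.73) and erythroid markers (control fasted 5, 0.099, control fasted 11, 0.12). The call of fatty acid synthesis, ribosomal proteins, monocyte markers, neutrophil markers and erythroid markers ended without any 1 of 3 to 5 arrays (adjusted p up to 0.441).

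Comparing fasted with fed cafeteria rats asks the same of rats made obese by diet. Among genes that glucocorticoids, the adrenal stress hormones, induce, Klf9 rose by 0.91 ± 0.18 (adjusted p = 0.0203), Sgk1 rose by 0.90 ± 0.22 (adjusted p = 0.0445), Mt1 rose by 0.66 ± 0.13 (adjusted p = 0.0178) and Per1 rose by 0.75 ± 0.18 (adjusted p = 0.0402), which encode a transcription factor, a kinase, a metal-binding protein and a clock component. Cxcl2 rose by 2.92 ± 0.71 (adjusted p = 0.0441), a 7.56-fold rise, and Ccl2 rose by 1.56 ± 0.28 (adjusted p = 0.0111), both attractants of white blood cells. Txnip rose by 0.77 ± 0.17 (adjusted p = 0.0271), which encodes an inhibitor of thioredoxin, and Cdkn1a rose by 0.96 ± 0.20 (adjusted p = 0.0219), which encodes an inhibitor of cell division. Bcl6 fell by 0.68 ± 0.15 (adjusted p = 0.0327), Lpar6 fell by 0.66 ± 0.097 (adjusted p = 0.00359) and Id3 fell by 0.87 ± 0.19 (adjusted p = 0.0291), the last encoding an inhibitor of transcription factors in lymphocytes.

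**Figure D2:**
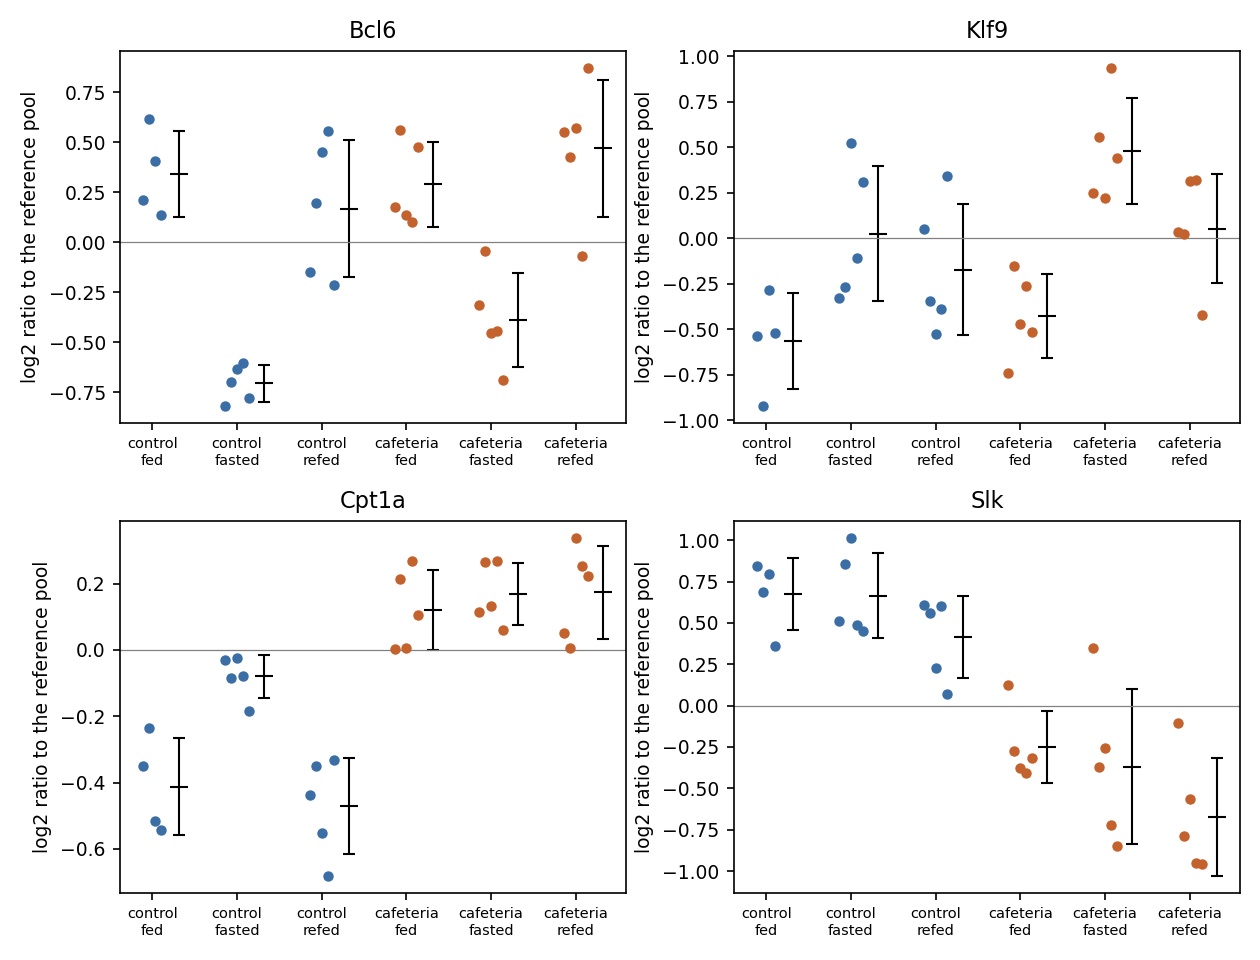
Log2 ratio of Bcl6, Klf9, Cpt1a and Slk in each array (points) by diet and feeding condition, with group means and SD (bars). Bcl6 averages -0.71 in control fasted and -0.39 in cafeteria fasted rats against 0.34 and 0.29 in fed rats, and Cpt1a is higher in each cafeteria group than in its control group.

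In this comparison 206 genes passed, of which 114 rose and 92 fell, with median changes of 0.51 and -0.44. The alternative values gave 222, 0, 202 and 252 genes (66 rises and 186 falls in the last), extraction run as a block 22 and leaving out 1 array 10 to 303. Each called gene named here differed in that direction in all 5 fasted rats. Of 23 measured glucocorticoid response genes, 5 rose over all genes and 12 adjusted over the list alone (mean 0.34, adjusted p = 2.81e-09, or 0.0266). In control rats the same list had a mean of 0.13 (adjusted p = 0.073), and the interaction of diet and fasting for it was 0.21 (adjusted p = 0.000263, or 0.32). Immediate early genes, which cells switch on within minutes of a stimulus, were higher (mean 0.35, adjusted p = 2.7e-06, or 0.38). None of 27 passed over all genes, and 10 rose and 1 fell adjusted over the list alone, with 1.06 for Atf3 (adjusted p = 0.0694) and 1.06 for Egr1 (adjusted p = 0.155). Inflammatory cytokines and receptors were higher (mean 0.35, adjusted p = 0.000866, or 0.501), with 2 of 25 rising over all genes and 8 adjusted over the list alone. Interferon response genes were higher (mean 0.26, adjusted p = 0.000866, or 0.628), with 1.17 for Cxcl10 (adjusted p = 0.0572) and 0.78 for Ifit1 (adjusted p = 0.606).

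Genes of sterol synthesis were lower in fasted cafeteria rats (mean -0.096, adjusted p = 0.00545, or 0.533), and Msmo1 fell by 0.52 ± 0.13 (adjusted p = 0.0461). B cell markers were lower (mean -0.14, adjusted p = 0.00545, or 0.628). The platelet marker mean changed by 0.11 (adjusted p = 0.568). The change of Cpt1a was 0.049 (adjusted p = 0.916). With slide as a block the median size of the changes of the 206 genes was 0.44 against 0.47, and 1 gene passed. Without 1 array, values moved for interferon response (cafeteria fasted 14, 0.13, adjusted p = 0.195) and B cells (any 1 of 4, -0.23 to -0.089). Any 1 of 3 arrays decided the call of B cell markers (adjusted p up to 0.104). Neutrophil markers had a mean of 0.26 (adjusted p = 0.0578).

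The fasting responses of both diets were compared gene by gene, to ask whether they were shared. The change of a gene in control rats and in cafeteria rats had a correlation of 0.471 across genes, which are not independent replicates. All 206 genes that passed in cafeteria rats had the same sign in control rats. Of the 43 that passed in control rats, 40 did in cafeteria rats. 15 falls passed in both diets, where lists independent of each other would share 0.0947. They held Bcl6, Scd2, Tlr6, Lpar6, Mterf1 and Spart. With the alternative values 6, 0, 3 and 1 genes were shared. There were 0 rises passing in both, against 0.0845 for independent lists.

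Comparing refed with fasted control rats asks how the cells respond to food after a fast. Platelet genes were among the falls. Gp1bb fell by 1.84 ± 0.36 (adjusted p = 0.00231), Treml1 fell by 1.95 ± 0.39 (adjusted p = 0.00246) and Pf4 fell by 1.79 ± 0.43 (adjusted p = 0.00774), which encode a subunit of the platelet receptor for von Willebrand factor, a platelet granule receptor and platelet factor 4. Me1 fell by 2.16 ± 0.35 (adjusted p = 0.000869), a 4.46-fold fall of malic enzyme, a source of NADPH for lipid synthesis, and Cst3 fell by 2.03 ± 0.34 (adjusted p = 0.00101), which encodes cystatin C. Genes that had fallen on fasting rose, and Bcl6 rose by 0.88 ± 0.15 (adjusted p = 0.0013). Id3 also rose, by 0.97 ± 0.19 (adjusted p = 0.00239).

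In this comparison 2263 genes passed, of which 803 rose and 1460 fell, with median changes of 0.30 and -0.59. The balance turned to 2951 rises and 971 falls in the authors' table, 1195 and 1207 with Cy5 alone and 25 and 785 with median centring. Each called gene named here differed in that direction in all 5 refed rats, except Cks2 with 4. Of 23 platelet and megakaryocyte markers, 22 fell (mean -1.40, adjusted p = 1.96e-21, or 0.345). With the platelet covariate 4 genes passed, and the calls of sterol synthesis (0.078, 0.188) and ribosomal proteins (0.031, 0.349) ended. Genes of sterol synthesis and uptake were higher (mean 0.14, adjusted p = 0.0119, or 0.929). 5 of 27 rose over all genes, against 9 rising and 1 falling adjusted over the list alone, and Msmo1 rose by 0.56 ± 0.13 (adjusted p = 0.00555), Dhcr7 rose by 0.37 ± 0.086 (adjusted p = 0.00607) and Fdft1 rose by 0.35 ± 0.092 (adjusted p = 0.0154). Ribosomal proteins were higher (mean 0.17, adjusted p = 3.23e-06, or 0.929), with 0 of 61 passing. ER chaperones and unfolded protein response genes were lower (mean -0.21, adjusted p = 0.0179, or 0.929), with 3 of 18 falling, and Hspa5 fell by 0.40 ± 0.098 (adjusted p = 0.00936), beside a mean of -0.34 for plasma cell markers (adjusted p = 0.172). Cell cycle genes were lower (mean -0.12, adjusted p = 0.0265, or 0.929), with 2 of 38 falling, Cks2 (-0.79) and Top2a (-0.50), and 1 rising, Lig1 (0.28).

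Among the metabolic genes named in advance, Cpt1a fell by 0.39 ± 0.076 (adjusted p = 0.0022), Fasn rose by 0.26 ± 0.076 (adjusted p = 0.0316) and Srebf2 rose by 0.34 ± 0.11 (adjusted p = 0.0405). Cpt1a encodes the enzyme that admits fatty acids to mitochondria for oxidation, Fasn encodes fatty acid synthase, and Srebf2 encodes a regulator of sterol synthesis. The change was 0.31 ± 0.11 for Srebf1 (adjusted p = 0.0703). Blocking on slide ended the call of cell cycle genes (-0.12, 0.0541), and the run block those of ER chaperones (-0.17, 0.087) and cell cycle genes (-0.11, 0.09). Leaving out 1 array moved sterol synthesis (control fasted 8, adjusted p = 0.0508), ER chaperones (control fasted 2, -0.038, adjusted p = 0.664), cell cycle (control fasted 2, -0.041, adjusted p = 0.563, control refed 9, adjusted p = 0.0741) and ribosomal proteins (control refed 15, 0.11).

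Comparing refed with fasted cafeteria rats asks the same of the cafeteria diet. Egr1 fell by 1.66 ± 0.34 (adjusted p = 0.012), Nr4a2 fell by 0.71 ± 0.17 (adjusted p = 0.0274) and Atf3 fell by 1.13 ± 0.28 (adjusted p = 0.0416), transcription factors among the immediate early genes. Cxcl2 fell by 2.94 ± 0.71 (adjusted p = 0.0332), Cxcl1 fell by 1.24 ± 0.29 (adjusted p = 0.031), Ccl2 fell by 1.42 ± 0.28 (adjusted p = 0.0101) and Cxcl10 fell by 1.24 ± 0.30 (adjusted p = 0.0343), all chemokines. Per1 fell by 0.75 ± 0.18 (adjusted p = 0.0309), Sgk1 fell by 0.85 ± 0.22 (adjusted p = 0.0469) and Mt1 fell by 0.61 ± 0.13 (adjusted p = 0.0162) among the glucocorticoid response genes, and Bcl6 rose by 0.86 ± 0.15 (adjusted p = 0.00637) and Lpar6 rose by 0.64 ± 0.097 (adjusted p = 0.00254).

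In this comparison 341 genes passed, of which 184 rose and 157 fell, with median changes of 0.42 and -0.45. The alternative values gave 234, 0, 153 and 143 genes and leaving out 1 array 74 to 520. Each called gene named here differed in that direction in all 5 refed rats. Immediate early genes were lower (mean -0.35, adjusted p = 3.02e-05, or 0.695), with 3 of 27 falling over all genes, and 8 falling and 1 rising adjusted over the list alone. Inflammatory cytokines and receptors were lower (mean -0.34, adjusted p = 0.00233, or 0.695), with 3 of 25 falling over all genes and 4 adjusted over the list alone. Interferon response genes were lower (mean -0.28, adjusted p = 0.000406, or 0.874), with 1 of 29 falling over all genes and 4 adjusted over the list alone. Glucocorticoid response genes were lower (mean -0.17, adjusted p = 0.00536, or 0.695), with 3 of 23 falling by either count.

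None of the markers of platelets, NK and cytotoxic cells or erythroid cells passed by either count. As lists, platelet markers were lower (mean -0.44, adjusted p = 0.000292, or 0.874). NK and cytotoxic cell markers were lower (mean -0.24, adjusted p = 0.00764, or 0.874), with -0.60 for Gzmb (adjusted p = 0.502), whose other probes had a median of 0.017. Erythroid markers were higher (mean 0.18, adjusted p = 0.0023, or 0.874), with 0.77 for Ahsp (adjusted p = 0.439). The change was -0.54 ± 0.17 for Txnip (adjusted p = 0.115). Single arrays moved glucocorticoid response (cafeteria refed 15, adjusted p = 0.0586), interferon response (cafeteria fasted 14, -0.15, adjusted p = 0.0955), NK markers (cafeteria fasted 14, -0.145, cafeteria refed 15, -0.059), platelets (cafeteria refed 3, -0.18, adjusted p = 0.0972) and erythroid markers (any 1 of 3, 0.11 to 0.305, cafeteria refed 15, adjusted p = 0.0586). The call of NK and cytotoxic markers ended without any 1 of 3 arrays (adjusted p up to 0.645).

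Refeeding was compared with fasting gene by gene, to ask whether it turned the fasting changes round. In control rats all 43 genes that passed on fasting had the opposite sign on refeeding, and all passed there. In cafeteria rats 206 of 206 had the opposite sign, and 144 passed. The fasted arrays enter both comparisons, which alone produced 96.6% and 95.3% opposite signs in data simulated without any refeeding response in control and cafeteria rats. With the fasted arrays split between the fasting and refeeding comparisons, the comparisons shared no array, so the simulated percentages are no baseline there either. Of as many genes ranked anew by the fasting change in 1 part, 99.3% (97.7% to 100% over 20 splits) and 96.2% (90.3% to 99.5%) had opposite signs. The covariance of the changes over genes was -0.0332 against -0.00751 simulated in control rats, and -0.0187 against -0.00754 in cafeteria rats.

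**Figure D3:**
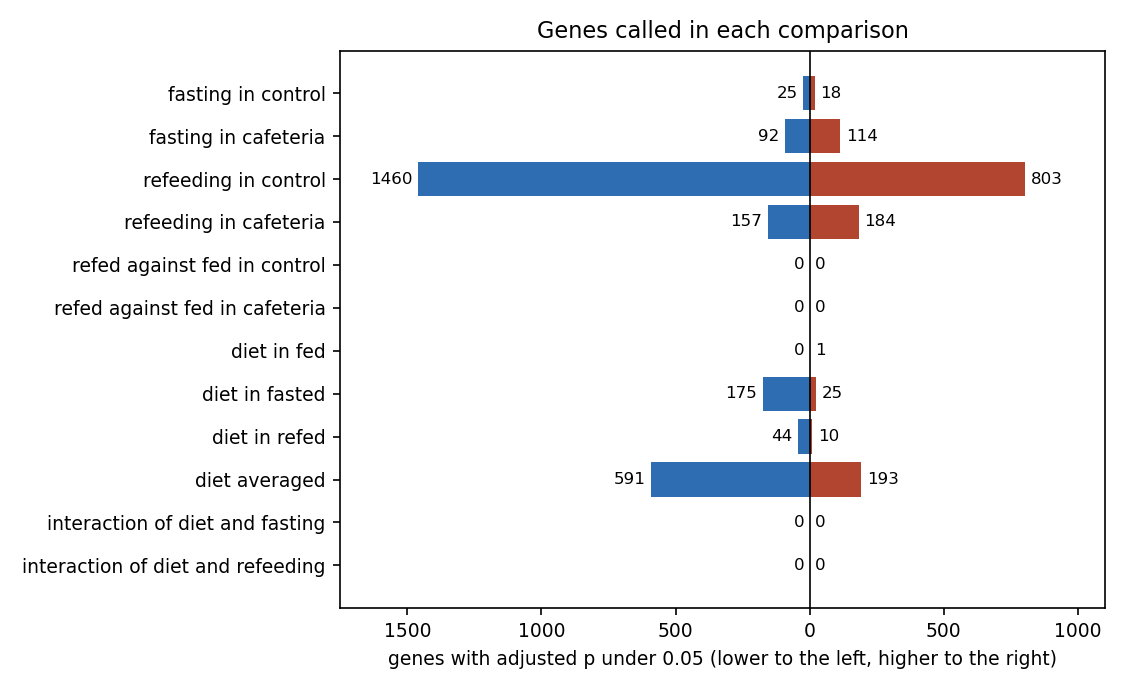
Number of genes with an adjusted p under 0.05 (horizontal axis, rises to the right and falls to the left) in each of the 12 comparisons. Refeeding in control rats has 803 rises and 1460 falls, and the diet averaged over feeding conditions 193 rises and 591 falls.

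Comparing refed with fed control rats asks whether refeeding brought expression back to the fed state. No gene passed in limma, and 1417 had an unadjusted p under 0.05, while with array weights 718 passed (178 rises, 540 falls). Among genes with a symbol, the smallest p-values belonged to -0.80 for Sap30l, -1.75 for Me1, -1.01 for Lims1, -0.67 for Pygl and -0.89 for Ap3s1, each with an adjusted p of 0.372. Platelet markers were lower (mean -0.91, adjusted p = 6.6e-26, or 0.0953), with 16 of 23 falling adjusted over the list alone. Ribosomal proteins, the building blocks of ribosomes, were higher (mean 0.25, adjusted p = 2.29e-27, or 0.125), with means of 0.055 and 0.43 in runs 1 and 2, 16 of 61 rising adjusted over the list alone, and 0.65 for Rpl7 (adjusted p = 0.372). Also higher were ribosome biogenesis genes (mean 0.10, adjusted p = 1.06e-07, or 0.0953), proteasome genes (mean 0.085, adjusted p = 3.89e-06, or 0.128), oxidative phosphorylation genes (mean 0.032, adjusted p = 0.014, or 0.651) and NK and cytotoxic cell markers (mean 0.22, adjusted p = 0.00451, or 0.914). Genes of fatty acid and triglyceride synthesis were lower (mean -0.12, adjusted p = 0.031, or 0.128). A slide block ended the call of oxidative phosphorylation (0.010, 0.366), and the platelet covariate those of fatty acid synthesis (-0.055, 0.221) and NK and cytotoxic markers (-0.0072, 0.985). Without 1 array, values moved for ribosomal proteins (control fed 4, 0.13), proteasome (control fed 7, 0.051) and NK markers (control refed 6, 0.12). Any 1 of 3 to 5 arrays decided the call of fatty acid synthesis, oxidative phosphorylation and NK and cytotoxic markers (adjusted p up to 0.185).

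Comparing refed with fed cafeteria rats asks the same of the cafeteria diet. No gene passed in limma, and 1038 had an unadjusted p under 0.05. Among genes with a symbol, the smallest p-values belonged to 0.40 for Tgif1 (adjusted p = 0.193), 0.21 for Or1f30, 0.41 for Tfrc, 0.48 for Gadd45a and 0.28 for Cenpv. NK and cytotoxic cell markers were lower (mean -0.35, adjusted p = 1.84e-09, or 0.283). Erythroid markers were higher (mean 0.30, adjusted p = 8.1e-09, or 0.283), with 0.88 for Slc4a1 (adjusted p = 1) and 0.89 for Rhd. Also higher were neutrophil markers (mean 0.23, adjusted p = 8.97e-05, or 0.298), T cell markers (mean 0.092, adjusted p = 0.0104, or 0.688), sterol efflux genes and LXR targets (mean 0.078, adjusted p = 0.0151, or 0.287), glucocorticoid response genes (mean 0.17, adjusted p = 0.000297, or 0.283) and FOXO and insulin-responsive genes (mean 0.097, adjusted p = 0.0214, or 0.283). Also lower were platelet markers (mean -0.33, adjusted p = 1.9e-05, or 0.663), sterol synthesis genes (mean -0.11, adjusted p = 4.29e-06, or 0.283) and cell cycle genes (mean -0.069, adjusted p = 0.0214, or 0.766). The run block ended the call of sterol efflux (0.056, 0.1) and cell cycle genes (-0.046, 0.245). Blocking on slide ended the call of sterol synthesis (-0.046, 0.144), sterol efflux (0.050, 0.169), glucocorticoid response genes (0.13, 0.0603), FOXO targets (0.095, 0.139) and cell cycle genes (-0.0056, 0.911), and the platelet covariate that of T cell markers (0.0575, 0.173). Leaving out 1 array moved sterol efflux (cafeteria fed 1, 0.040, cafeteria refed 15, 0.050), T cells (any 1 of 3, 0.0425 to 0.14), NK markers (cafeteria refed 15, -0.16), neutrophils (cafeteria refed 6, 0.12, adjusted p = 0.0871, cafeteria refed 15, 0.14) and platelets (any 1 of 3, -0.54 to -0.072, cafeteria refed 3, adjusted p = 0.304). For sterol efflux, FOXO targets, cell cycle genes and T cell markers the call ended without any 1 of 3 to 5 arrays (adjusted p up to 0.416).

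Comparing cafeteria with control rats that ate freely asks how the diet changed the cells apart from fasting. Cpt1a rose by 0.53 ± 0.081 (adjusted p = 0.0138), a 1.45-fold rise, and it was the 1 gene that passed, with 1098 at an unadjusted p under 0.05. Its group mean was 0.12 ± 0.12 (SD, n = 5) in cafeteria fed against -0.41 ± 0.14 (SD, n = 4) in control fed rats. Next among genes with a symbol came -0.65 ± 0.12 for Fyco1 (adjusted p = 0.123), -1.16 ± 0.23 for Ptpn11 (adjusted p = 0.136), -0.56 ± 0.12 for Jak1 (adjusted p = 0.257), -0.92 ± 0.20 for Slk (adjusted p = 0.257) and -0.91 ± 0.18 for Tlk1 (adjusted p = 0.135), whose other probe had 0.008. Genes of fatty acid oxidation and PPAR targets were higher as a list (mean 0.20, adjusted p = 0.00106, or 0.0744), with 1 of 36 rising by either count. Their median was 0.066, and without Slc27a2, left out after seeing the data, the mean was 0.081 (adjusted p = 0.00359). B cell markers were higher (mean 0.20, adjusted p = 7.06e-05, or 0.855), with 0.41 for Cd72 (adjusted p = 1). T cell markers were lower (mean -0.12, adjusted p = 0.000445, or 0.855), with -0.51 for Bcl11b (adjusted p = 0.641) and -0.46 for Cd3e (adjusted p = 0.934). Higher too were ribosomal proteins (mean 0.14, adjusted p = 5.96e-08, or 0.855), proteasome genes (mean 0.064, adjusted p = 0.0103, or 0.855) and NK and cytotoxic cell markers (mean 0.17, adjusted p = 0.0352, or 0.855). Platelet markers were lower (mean -0.26, adjusted p = 0.00359, or 0.855). The change of Slc27a2, a fatty acid transporter, was 4.198 ± 1.41 (adjusted p = 0.814).

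When slide was a block, 0 genes passed in fed rats, and the change of Cpt1a was 0.56 (adjusted p = 0.196). It was 0.54 within extraction run 1, and 0.59 within run 2, which holds 1 cafeteria fed rat. Without cafeteria fed 10, control fed 7 or control fed 13, 0 genes passed. The run block ended the call of proteasome genes (0.052, 0.0805), NK and cytotoxic markers (0.14, 0.13) and platelet markers (-0.13, 0.182). With slide as a block, the call ended for proteasome genes (0.042, 0.184) and platelet markers (-0.13, 0.152). It ended with the platelet covariate for proteasome genes (0.053, 0.0722) and NK and cytotoxic markers (0.11, 0.249). Single arrays moved ribosomal proteins (control fed 4, 0.027, adjusted p = 0.726, cafeteria fed 4, 0.093), proteasome (control fed 7, 0.0305, adjusted p = 0.512, control fed 4, adjusted p = 0.1), T cells (any 1 of 4, -0.18 to -0.066, control fed 13, adjusted p = 0.0745, cafeteria fed 13, adjusted p = 0.0913), NK markers (cafeteria fed 7, 0.066) and platelets (any 1 of 5, -0.41 to -0.011). The call of NK and cytotoxic markers and platelet markers ended without any 1 of 3 to 4 arrays (adjusted p up to 0.948).

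Comparing cafeteria with control rats after a fast asks whether the diets differ in the fasted state. Ptpn11 fell by 1.51 ± 0.22 (adjusted p = 0.00113), a 2.85-fold fall, and Shoc2 fell by 1.24 ± 0.24 (adjusted p = 0.0134). They encode a phosphatase and a scaffold that act in growth factor signalling through RAS. Tlk1 fell by 1.09 ± 0.17 (adjusted p = 0.00187) and Slk fell by 1.03 ± 0.19 (adjusted p = 0.00671), which encode kinases, and Calr fell by 0.96 ± 0.19 (adjusted p = 0.0161), which encodes the ER chaperone calreticulin. Tgfa rose by 0.73 ± 0.16 (adjusted p = 0.0233), a ligand of the EGF receptor, and Alas1 rose by 0.34 ± 0.074 (adjusted p = 0.0258), the first enzyme of haem synthesis.

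Of the 200 genes that passed in fasted rats, 25 rose and 175 fell, with median changes of 0.32 and -0.51. The alternative values gave 13, 24, 13 and 9 genes and leaving out 1 array 58 to 365. Each called gene named here differed in that direction in all 5 cafeteria rats. Further falls were Sytl4 (-1.09), Pde5a (-1.13), Mylk (-0.95), Lims1 (-0.98) and Rac1 (-0.92), and Polr2d rose (0.44). Platelet markers were lower (mean -0.63, adjusted p = 7.49e-09, or 0.505), and Rgs18 fell by 1.16 ± 0.28 (adjusted p = 0.0468), the 1 of 23 that fell. Neutrophil markers were higher (mean 0.41, adjusted p = 0.000623, or 0.505), with 0 of 23 passing over all genes and 5 rising adjusted over the list alone, and 1.32 for Defa5 (adjusted p = 0.104) and 1.08 for S100a9 (adjusted p = 0.302). Inflammatory cytokines and receptors were higher (mean 0.25, adjusted p = 0.000145, or 0.44), with 1.22 for Cxcl2 (adjusted p = 0.429). Glucocorticoid response genes were higher (mean 0.27, adjusted p = 4.25e-05, or 0.334), with 3 of 23 rising adjusted over the list alone, and 0.56 for Tsc22d3 (adjusted p = 0.0914). Other lists higher in these rats were monocyte markers (mean 0.17, adjusted p = 0.0031, or 0.505), immediate early genes (mean 0.22, adjusted p = 0.00481, or 0.505) and ribosomal proteins (mean 0.066, adjusted p = 0.0191, or 0.939).

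ER chaperones and unfolded protein response genes were lower in fasted cafeteria rats (mean -0.27, adjusted p = 0.000238, or 0.505), with 2 of 18 falling, Calr (-0.96) and Dnajc3 (-0.65). Cell cycle genes were lower (mean -0.093, adjusted p = 0.00743, or 0.613), and so were plasma cell markers (mean -0.55, adjusted p = 0.00803, or 0.613), with -1.11 for Tnfrsf17 (adjusted p = 0.404) and -0.91 for Mzb1 (adjusted p = 0.352). The change of Cpt1a was 0.25 ± 0.076 (adjusted p = 0.117). The run block ended the call of cell cycle genes (-0.071, 0.0518) and plasma cell markers (-0.38, 0.0701). A slide block ended the call of ER chaperones (-0.17, 0.0757), cell cycle genes (-0.034, 0.28), ribosomal proteins (0.057, 0.152), plasma cell markers (-0.30, 0.204) and monocyte markers (0.13, 0.0757), and the platelet covariate that of ribosomal proteins (0.0051, 0.675). Without 1 array, values moved for ER chaperones (control fasted 2, -0.10, adjusted p = 0.132), immediate early genes (control fasted 2, adjusted p = 0.057), cell cycle (any 1 of 3, -0.15 to -0.0095), ribosomal proteins (control fasted 14, adjusted p = 0.112, cafeteria fasted 5, adjusted p = 0.122), plasma cells (control fasted 2, -0.11, adjusted p = 0.613) and monocytes (cafeteria fasted 5, 0.11). Any 1 of 3 arrays decided the call of cell cycle genes (adjusted p up to 0.573).

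Comparing cafeteria with control rats after refeeding asks whether the diets differ in the refed state, which holds any lasting effect of the diet beside the response to the meal. Cpt1a rose by 0.65 ± 0.076 (adjusted p = 0.000144), a 1.56-fold rise, with 0.17 ± 0.14 (SD, n = 5) in cafeteria and -0.47 ± 0.15 (SD, n = 5) in control refed rats. Tgm2 rose by 1.20 ± 0.25 (adjusted p = 0.0362), Arg1 rose by 0.71 ± 0.14 (adjusted p = 0.0194) and Pon3 rose by 0.83 ± 0.18 (adjusted p = 0.0433), which encode transglutaminase 2, arginase and a paraoxonase. Slk fell by 1.09 ± 0.19 (adjusted p = 0.0108), Shoc2 fell by 1.37 ± 0.24 (adjusted p = 0.0116) and Ddx6 fell by 1.04 ± 0.20 (adjusted p = 0.0217), the last encoding a helicase that acts in the decay of messenger RNA.

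Of the 54 genes that passed in refed rats, 10 rose and 44 fell, with median changes of 0.73 and -0.64. The alternative values gave 88, 0, 114 and 291 genes and leaving out 1 array 4 to 139. Each called gene named here differed in that direction in all 5 cafeteria rats. Erythroid markers were higher (mean 0.42, adjusted p = 1.35e-09, or 0.261), with 0 of 31 passing over all genes and 9 rising adjusted over the list alone, and 1.47 for Ahsp (adjusted p = 0.166). NK and cytotoxic cell markers were lower (mean -0.40, adjusted p = 2.63e-09, or 0.309), with -0.74 for Ccl5 (adjusted p = 0.434). Other lower lists were ribosomal proteins (mean -0.12, adjusted p = 1.68e-07, or 0.567), ribosome biogenesis genes (mean -0.085, adjusted p = 0.000332, or 0.294) and proteasome genes (mean -0.033, adjusted p = 0.0293, or 0.625). Genes of sterol synthesis and uptake were lower (mean -0.13, adjusted p = 4.67e-06, or 0.19), with 2 of 27 falling adjusted over the list alone. The change was -0.44 ± 0.10 for Lss (adjusted p = 0.059) and -0.38 ± 0.11 for Srebf2 (adjusted p = 0.138), whose other probe had 0.20. Genes of sterol efflux and LXR targets were higher (mean 0.13, adjusted p = 0.00999, or 0.309), with 0.57 for Abca1 (adjusted p = 0.122) and 0.45 for Nr1h3 (adjusted p = 0.354), an exporter of cholesterol and the sterol receptor that induces it.

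Further lists higher in refed cafeteria rats were fatty acid oxidation genes and PPAR targets (mean 0.047, adjusted p = 0.0013, or 0.113, and 0.10 without Slc27a2), glucocorticoid response genes (mean 0.17, adjusted p = 0.0209, or 0.481), neutrophil markers (mean 0.29, adjusted p = 0.000126, or 0.362), B cell markers (mean 0.13, adjusted p = 0.0246, or 0.639) and platelet markers (mean 0.33, adjusted p = 0.00188, or 0.644). Further lower ones were ER chaperones (mean -0.13, adjusted p = 0.0262, or 0.644) and T cell markers (mean -0.094, adjusted p = 0.0029, or 0.567). With slide as a block 1 gene passed. With the run block the call ended for ER chaperones (-0.11, 0.0515) and proteasome genes (-0.024, 0.0672). Blocking on slide ended the call of sterol synthesis (-0.049, 0.13), glucocorticoid response genes (0.14, 0.139), ER chaperones (-0.046, 0.639), proteasome genes (-0.0016, 0.598), T cell markers (-0.054, 0.0897) and platelet markers (-0.016, 0.639). The platelet covariate ended the call of sterol efflux (0.094, 0.0616), ER chaperones (-0.11, 0.0722), proteasome genes (-0.018, 0.169) and B cell markers (0.076, 0.325). Leaving out 1 array moved sterol efflux (cafeteria refed 6, adjusted p = 0.102), fatty acid oxidation (any 1 of 6, 0.019 to 0.079), ribosomal proteins (control refed 15, -0.067), proteasome (any 1 of 3, -0.020 to -0.015), T cells (cafeteria refed 9, -0.060), B cells (cafeteria refed 15, 0.089), NK markers (cafeteria refed 15, -0.21), neutrophils (cafeteria refed 6, 0.18) and platelets (any 1 of 3, 0.12 to 0.585). For glucocorticoid response genes, ER chaperones, proteasome genes, B cell markers and platelet markers the call ended without any 1 of 3 to 5 arrays (adjusted p up to 0.383).

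Averaging the difference between diets over the feeding conditions asks for the effect of the diet whatever the rats had last eaten. Cpt1a rose by 0.48 ± 0.045 (adjusted p = 7.46e-07), a 1.39-fold rise, and Angptl4 rose by 0.30 ± 0.059 (adjusted p = 0.0027), which encodes a PPAR target that inhibits lipoprotein lipase. Ptpn11 fell by 1.14 ± 0.13 (adjusted p = 8.83e-06), Shoc2 fell by 1.21 ± 0.14 (adjusted p = 1.76e-05), Slk fell by 1.01 ± 0.11 (adjusted p = 7.36e-06) and Calr fell by 0.82 ± 0.11 (adjusted p = 9.04e-05). Abca1 rose by 0.40 ± 0.089 (adjusted p = 0.00859) and Nr1h3 rose by 0.33 ± 0.094 (adjusted p = 0.0483), and Lss fell by 0.33 ± 0.059 (adjusted p = 0.00106), which encodes lanosterol synthase.

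**Figure D4:**
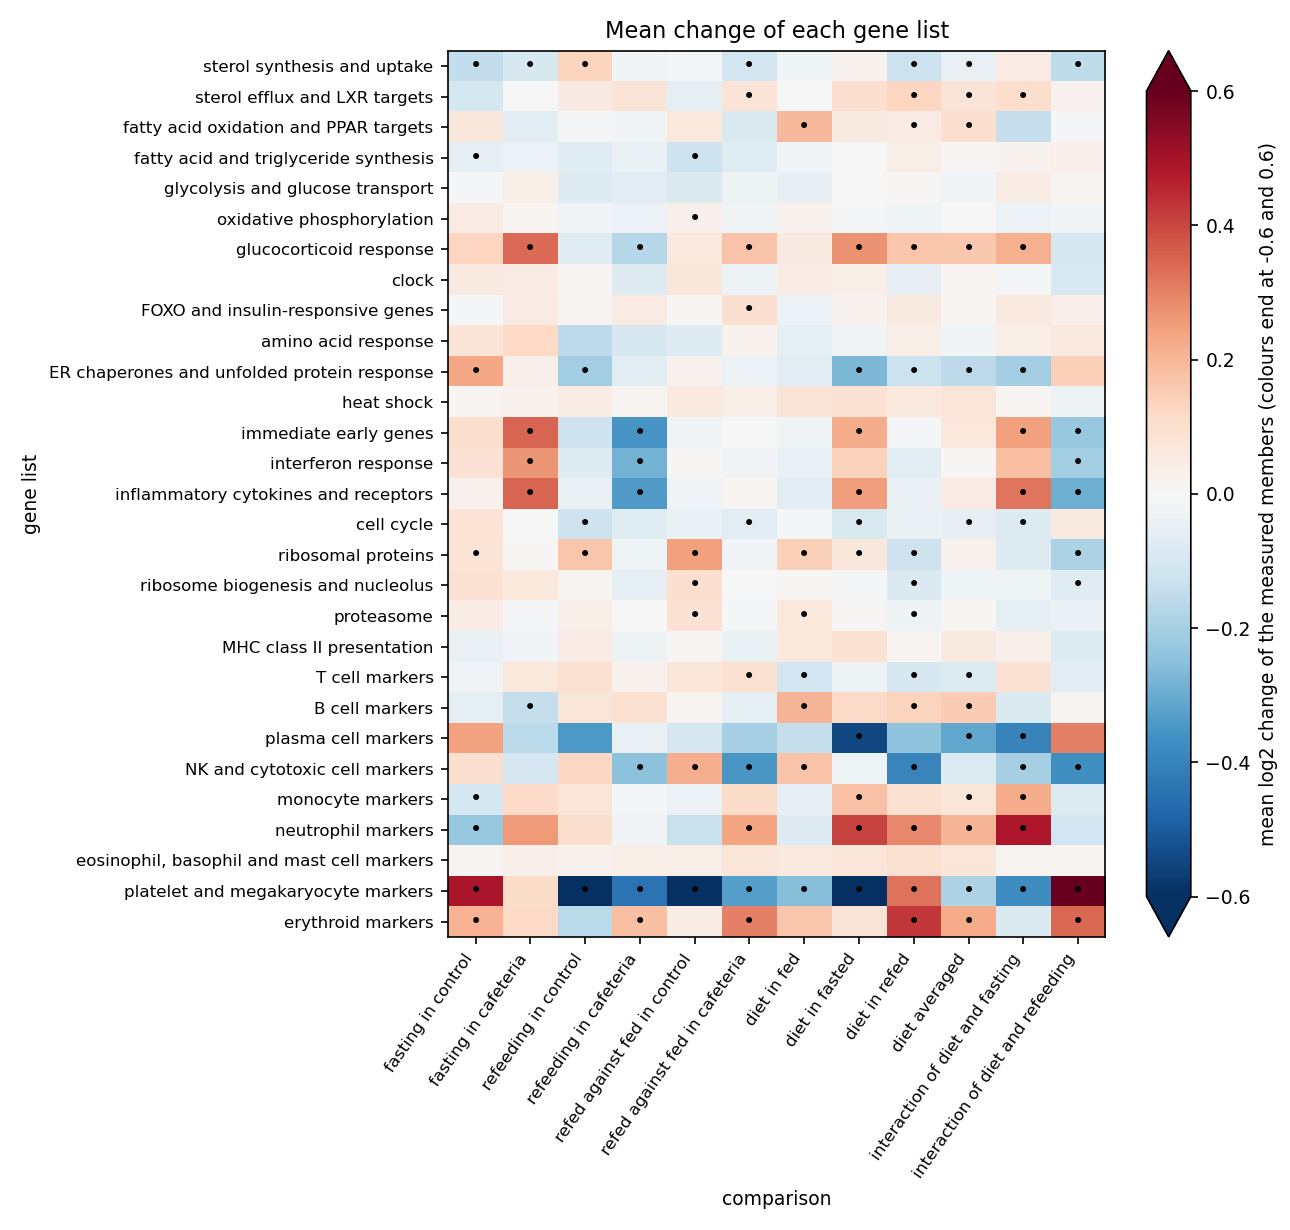
Mean log2 change of the measured members of each of the 29 gene lists (vertical axis) in each of the 12 comparisons (horizontal axis), as colour from -0.6 to 0.6, with a dot where camera's adjusted p was under 0.05. The platelet and megakaryocyte markers have -1.40 in refed against fasted control rats and 0.49 in fasted against fed control rats.

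Averaged over conditions, 784 genes passed, of which 193 rose and 591 fell, with median changes of 0.20 and -0.31. Median centring gave 54 genes. Further falls were Tlk1 (-0.90) and Wac (-0.95). Genes of fatty acid oxidation and PPAR targets were higher (mean 0.10, adjusted p = 0.000667, or 0.0384), with 2 of 36 rising by either count. Glucocorticoid response genes were higher (mean 0.16, adjusted p = 0.000667, or 0.416), with 2 of 23 rising over all genes and 3 adjusted over the list alone, among them Tsc22d3 (0.37). Genes of sterol efflux and LXR targets were higher (mean 0.075, adjusted p = 0.0403, or 0.62). Lists that were lower held sterol synthesis genes (mean -0.044, adjusted p = 0.0403, or 0.62), ER chaperones (mean -0.16, adjusted p = 0.000667, or 0.62) and cell cycle genes (mean -0.049, adjusted p = 0.0176, or 0.687). Srebf2 fell by 0.24 ± 0.062 (adjusted p = 0.0254), and its other probe had 0.14.

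Among cell type markers averaged over conditions, erythroid markers were higher (mean 0.22, adjusted p = 0.000667, or 0.62), with 3 of 31 rising over all genes and 7 adjusted over the list alone, among them Ahsp (0.99). Neutrophil markers were higher (mean 0.21, adjusted p = 0.00265, or 0.62), with 3 of 23 rising over all genes and 5 adjusted over the list alone, among them Camp (0.80), an antimicrobial peptide of neutrophils. B cell markers were higher (mean 0.15, adjusted p = 0.000667, or 0.62), among them Cd72 (0.47) and Cd37 (0.16), as were monocyte markers (mean 0.072, adjusted p = 0.0289, or 0.62), among them Spi1 (0.31). T cell markers were lower (mean -0.080, adjusted p = 0.000752, or 0.62), among them Bcl11b (-0.41), as were plasma cell markers (mean -0.31, adjusted p = 0.0138, or 0.62), with -0.66 for Tnfrsf17 (adjusted p = 0.404). Platelet markers were lower (mean -0.19, adjusted p = 0.00301, or 0.704). With the run block the call ended for sterol synthesis (-0.042, 0.0575), sterol efflux (0.069, 0.059) and monocyte markers (0.0648, 0.0564). With slide as a block, the call ended for sterol synthesis (-0.025, 0.321), sterol efflux (0.060, 0.146), cell cycle genes (-0.022, 0.267), plasma cell markers (-0.26, 0.0642), monocyte markers (0.041, 0.26) and erythroid markers (0.15, 0.062). Single arrays moved ER chaperones (control fasted 2, -0.099), cell cycle (control fasted 2, -0.021, adjusted p = 0.127, cafeteria fasted 11, adjusted p = 0.0539), plasma cells (control fasted 2, -0.17, adjusted p = 0.0972) and platelets (control fed 4, -0.105, adjusted p = 0.0751, cafeteria refed 3, -0.10, adjusted p = 0.0662). The call of sterol synthesis, sterol efflux and monocyte markers ended without any 1 of 8 to 12 arrays (adjusted p up to 0.114).

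The interaction of diet and fasting asks whether the fasting response differed between the diets. No gene passed in limma, and 777 had an unadjusted p under 0.05. In both interactions, a higher or lower response means the signed change in cafeteria rats minus that in control rats. Among genes with a symbol, the smallest p-values belonged to -0.27 for Dusp15, -0.69 for Rpgrip1 and -0.27 for Zyg11b, each with an adjusted p of 1. Neutrophil markers had a higher fasting response in cafeteria rats (mean 0.48, adjusted p = 1.99e-05, or 0.465), with 1.41 for S100a8 and 1.41 for S100a9, which encode calcium-binding proteins of neutrophils. Inflammatory cytokines and receptors had a higher response (mean 0.32, adjusted p = 6e-05, or 0.32), with 2.19 for Cxcl2 and 1.17 for Il1b. A higher response was also called for immediate early genes (mean 0.25, adjusted p = 0.00128, or 0.63), monocyte markers (mean 0.22, adjusted p = 0.00128, or 0.63) and sterol efflux genes and LXR targets (mean 0.11, adjusted p = 0.0497, or 0.636). A lower response was called for platelet markers (mean -0.38, adjusted p = 0.000577, or 0.667), ER chaperones (mean -0.20, adjusted p = 0.00677, or 0.667), cell cycle genes (mean -0.080, adjusted p = 0.0442, or 0.667), plasma cell markers (mean -0.40, adjusted p = 0.0497, or 0.667) and NK and cytotoxic cell markers (mean -0.20, adjusted p = 0.0442, or 0.667). The adjusted p of each gene named here was 1, and the value was -5.03 ± 1.94 for Slc27a2 (adjusted p = 1). With the run block the call ended for sterol efflux (0.074, 0.209), ER chaperones (-0.12, 0.18), cell cycle genes (-0.046, 0.328), plasma cell markers (-0.16, 0.422) and NK and cytotoxic markers (-0.10, 0.422). A slide block ended the call of sterol efflux (0.069, 0.367), ER chaperones (-0.0014, 0.913), immediate early genes (0.20, 0.0545), cell cycle genes (0.033, 0.79), plasma cell markers (0.12, 0.913) and NK and cytotoxic markers (-0.14, 0.442). Without 1 array, values moved for sterol efflux (control fed 4, 0.065, cafeteria fed 1, 0.069), ER chaperones (control fasted 2, -0.032, adjusted p = 0.695), immediate early genes (cafeteria fed 1, adjusted p = 0.0563), cell cycle (any 1 of 4, -0.135 to 0.0040), plasma cells (any 1 of 4, -0.61 to 0.031), NK markers (any 1 of 3, -0.30 to -0.094), monocytes (cafeteria fed 1, 0.14, adjusted p = 0.0751) and platelets (any 1 of 3, -0.62 to -0.225). Any 1 of 9 to 10 arrays decided the call of sterol efflux, cell cycle genes, plasma cell markers and NK and cytotoxic markers (adjusted p up to 0.994).

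The interaction of diet and refeeding asks the same of the refeeding response. No gene passed in limma, and 1818 had an unadjusted p under 0.05. Among genes with a symbol, the smallest p-values belonged to 0.51 ± 0.11 for Mast4 (adjusted p = 0.333), 0.58 ± 0.13 for Bet1 (adjusted p = 0.468) and 0.28 ± 0.065 for Dusp15 (adjusted p = 0.468). The fall of the platelet markers was smaller in cafeteria rats (mean 0.96, adjusted p = 4.47e-14, or 0.491), with 1.50 for Mmrn1 (adjusted p = 0.64), and the response of erythroid markers was higher (mean 0.34, adjusted p = 1.47e-05, or 0.515). Ribosomal proteins had a lower response in cafeteria rats (mean -0.19, adjusted p = 1.81e-09, or 0.555). NK and cytotoxic cell markers had a lower response (mean -0.37, adjusted p = 0.00011, or 0.585), with -0.77 for Xcl1 (adjusted p = 0.679). Lower refeeding responses were also called for ribosome biogenesis genes (mean -0.074, adjusted p = 0.00855, or 0.515), sterol synthesis genes (mean -0.15, adjusted p = 0.000162, or 0.491), inflammatory cytokines and receptors (mean -0.29, adjusted p = 0.000537, or 0.491), immediate early genes (mean -0.23, adjusted p = 0.00867, or 0.585) and interferon response genes (mean -0.20, adjusted p = 0.018, or 0.776). The run block ended the call of interferon response genes (-0.17, 0.0549). The platelet covariate ended the call of immediate early genes (-0.165, 0.106), ribosome biogenesis (-0.045, 0.299), NK and cytotoxic markers (-0.13, 0.143) and erythroid markers (0.073, 0.185). Leaving out 1 array moved interferon response (cafeteria fasted 14, -0.069), ribosome biogenesis (cafeteria refed 15, adjusted p = 0.0526) and NK markers (cafeteria refed 15, -0.18). For immediate early genes and interferon response genes the call ended without any 1 of 3 to 5 arrays (adjusted p up to 0.375).

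Of the 29 lists, 6 were called in no comparison of the main fit. They were glycolysis and glucose transport, whose mean change on fasting was -0.011 in control and 0.035 in cafeteria rats, the clock genes (0.054 and 0.049), the amino acid response (0.079 and 0.12), heat shock (0.012 and 0.023), MHC class II presentation (-0.044 and -0.015) and eosinophil, basophil and mast cell markers (0.018 and 0.033). The lowest adjusted p among them was 0.077, for the clock genes in the interaction of diet and refeeding.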

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

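The tests of slide, of single probes, of the response apart from the platelet markers and of platelets in fasted cafeteria rats, and the values of the amplification reach by run and by array, were chosen only after the result was seen, and so was the stricter reading of the reach. An array stood far from the other arrays of its group in 16 of 252 groups of list means and metabolic genes tested, and chance does so in about 1 in 20 groups. Among list means (log2 ratio), control fasted 2 stood apart for ER chaperones (0.86, others up to 0.0466), cell cycle (0.467, others up to 0.11) and proteasome genes (0.0401, others up to -0.0741). Control fed 4 stood apart for immediate early genes (-0.298, others from -0.0569) and B cell markers (0.124, others up to -0.146). Others were cafeteria fasted 14 for interferon response genes (0.663, others up to 0.0688), cafeteria fasted 8 for proteasome genes (0.0272, others up to -0.0643) and control refed 9 for B cell markers (0.182, others up to -0.124). Cafeteria refed 15 stood apart for NK and cytotoxic markers (-1.04, others from -0.227), cafeteria fed 7 for erythroid markers (-0.287, others from -0.0889) and control refed 3 for fatty acid synthesis (-0.158, others from -0.0537). Among genes, these included Slc27a2 in control fed 1 (-0.316, others up to -4.14), Ppara in cafeteria refed 3 (0.0549, others up to 0.0143), Ucp2 in control refed 12 (0.104, others up to -0.212) and Insr in control fasted 5 (0.224, others up to -0.00215).

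The fasting response differed between the diets, by camera at the preset correlation, for sterol efflux (0.107), glucocorticoid response (0.212), ER chaperones (-0.202), immediate early genes (0.246), inflammatory cytokines (0.323), cell cycle (-0.08), plasma cells (-0.4), NK cells (-0.199), monocytes (0.224), neutrophils (0.485) and platelets (-0.375). The refeeding response differed for sterol synthesis (-0.152), immediate early genes (-0.227), interferon response (-0.205), inflammatory cytokines (-0.294), ribosomal proteins (-0.191), ribosome biogenesis (-0.0737), NK cells (-0.368), platelets (0.959) and erythroid cells (0.345). These are mean log2 differences, cafeteria minus control, and 0 of these 20 calls held with an estimated correlation.

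In 100 splits of the arrays into groups of the same sizes, the real one included, on genes measured on every array, as many genes as in the real split passed in 1 split for fasting in control rats (42 genes, highest other split 4), fasting in cafeteria rats (206, 68), refeeding in control rats (2250, 38), refeeding in cafeteria rats (339, 22), the diet in fasted rats (205, 112), in refed rats (54, 45) and averaged (780, 2). For these, chance is unlikely, not excluded, and slide and run were not held even in the splits. With slide as a block 1 gene passed for fasting in cafeteria rats and 1 for the diet in refed rats, which gave 0 with only the compared groups and 4 without cafeteria refed 15 or control refed 3. Chance stays open for the diet in fed rats (7 splits, 2 genes, highest other 321). The splits decide nothing for refed against fed control rats (0 genes, highest other 4), refed against fed cafeteria rats (0, 236), the interaction with fasting (0, 29) and the interaction with refeeding (0, 1), since all 100 splits reach a real count of 0. The splits with 321, 236 and 29 genes point to sample structure apart from the groups, whose source was not found. Cafeteria fed and refed arrays split by extraction run gave 0 genes.

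The first pattern is the set of 1460 genes that fell on refeeding in control rats. Slide as the cause is argued against by a median ratio of 1.09 between the changes with and without slide as a block. Another amount of platelets or of their RNA among the isolated cells is a candidate explanation, since within groups the mean of 1425 of these genes not among the markers followed the platelet marker mean with r = 0.968 over 29 arrays (rho = 0.964, permutation p = 1e-05 for each, the smallest possible, 0.951 without the 2 farthest arrays, 0.955 in run 1 and 0.979 in run 2). A response to refeeding apart from the platelet markers cannot be told apart, as a median share of 0.283 of the change was left with the marker mean as a covariate (-0.589 to -0.154, with standard errors 1.14 times as large), and the marker mean itself differs between the groups. Whether feeding changes the number of platelets in the blood or their carry-over through the gradient stays open.

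The second pattern is the set of 591 genes that fell with the cafeteria diet averaged over conditions, such as Ptpn11 and Slk. Slide as the cause is argued against by a ratio of 0.982. The signal of single probes cannot be told apart from that of whole transcripts: the other probes of 157 genes had a slope of 0.31 on the tested probe (medians -0.0633 and -0.333), against 0.643 for refeeding in control rats. Another amplification reach along transcripts and an effect of the diet stay open. The diet difference was higher at the 3' than the 5' probe by a median of 0.2 in 124 pattern genes. It was 0.188 in run 1 and 0.167 in run 2, against 0.03 in all genes (0.0381 and -0.000942). Choosing genes by 1 probe's fall can itself make a gap, which all genes lack. Per array, the mean 3' minus 5' difference was 0.0493 higher with the cafeteria diet over 2295 genes (permutation p = 0.00109). Within runs it was 0.03 (permutation p = 0.0822). The median passed the bound set beforehand, which ignored that choice. The stricter reading, a gap of all genes in both runs, was not met. Of 12 probes in the mitochondrial ribosomal RNA region, looked at after the values were seen, 11 fell as well (median -0.669), against 1 of 37 in the rest of that genome (median -0.0484), which stays open too.

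The third pattern is the set of 206 genes changed by fasting in cafeteria rats, whose fed arrays lay mostly in extraction run 1 and fasted arrays in run 2. The extraction run as the whole cause is argued against by a slope of 0.00518 (jackknife SE 0.123) of the run difference within control groups on the change. With run as a block, tried after seeing the data, 22 genes passed: the median change went from 0.47 to 0.46, with standard errors 1.1 times as large, and 206 of 206 had the same sign. A part of the run, or of the slides that make it up, in single genes stays open. Argued against is another amount of platelets, by a median share of 1.01 left with the marker mean as a covariate. A response to fasting present in both diets is consistent with a share of 1 of these genes with the same sign in control rats. Under a slide block 1 gene passed, while the median change went from 0.47 to 0.441 and standard errors to 1.08 times their size. A difference in size between the diets stays open.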

How the results depend on the processing

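The platelet covariate, the extraction run as a block, each run alone and the list without Slc27a2 were chosen after seeing the data, and the cause of the changes below was not tested unless named. Refed against fed counts in cafeteria rats and both interaction counts stayed at 0 under each alternative except single runs, and the averaged diet count stayed within 1.5 times of 784 except with median centring and single runs. With the software's processed signals 9 genes passed for fasting in control rats, 3 for the diet in fed (1 rise, 2 falls), 13 in fasted and 88 in refed rats, 6 falls were shared by both fasting responses, and ribosomal proteins took the other direction on fasting in control rats (adjusted p = 0.0414, range 0.0002338 to 0.8519 over its alternatives). With median centring 2 genes passed for fasting in control (2 rises), 0 in cafeteria rats, 810 for refeeding in control (25 rises, 785 falls), 0 in cafeteria rats, 0 for the diet in fed, 24 in fasted, 0 in refed rats and 54 averaged, with 0 shared falls. With Cy5 alone 3 genes passed for fasting in control rats (3 falls), 153 for refeeding in cafeteria rats, 13 for the diet in fasted (13 falls) and 114 in refed rats, 3 falls were shared, refeeding in control rats had 1195 rises and 1207 falls, Cpt1a had -0.004311 for fasting in cafeteria rats and Polr2d -0.002081 for the diet in fasted rats. Values of the authors' table gave 1 gene for fasting in control rats (1 fall), 3922 for refeeding in control (2951 rises, 971 falls) and 143 in cafeteria rats, 9 for the diet in fasted and 291 in refed rats (17 rises, 274 falls), 1 fall was shared, and Cpt1a had -0.03006 for fasting in cafeteria rats. That table also gave 66 rises and 186 falls for fasting in cafeteria rats and 404 and 461 for the diet averaged. The median change of all genes was 0.153 in it for refeeding and 0.134 for refed against fed in control rats, 0.129 for the diet in fed rats and -0.145 for the interaction with refeeding, and 0.101 with median centring for the diet in refed rats. Leaving the filter out, 15 genes passed for fasting in control rats, and with signal required on all arrays 2 for the diet in fed rats. Signal over background limits the genes tested, as those near background on most arrays were left out. With every probe tested 23 passed for fasting in control rats, 302 for the diet in fasted and 97 in refed rats. With only the compared groups in the fit, and so fewer arrays to estimate the spread, 68 passed for fasting and 89 for refeeding in cafeteria rats, 0 for the diet in fed, 423 in fasted and 0 in refed rats. With array weights 120 passed for fasting in control, 70 for refeeding in cafeteria, 718 for refed against fed in control rats, 2 for the diet in fed, 132 in fasted and 145 in refed rats. Slide as a block left 16 for fasting in control, 1 in cafeteria rats, 0 for the diet in fed and 1 in refed rats. With the replicate block (rats of 1 number in both diets) 0 passed for the diet in fed and 139 in refed rats, and the numbers did not pair rats, since r lay between -0.151 and 0.208 in 14 pairs, with 2 over 0.1, and 5 of 28 arrays were closest to their partner. With the platelet covariate 11 passed for fasting and 4 for refeeding in control rats, 30 for the diet in fed and 419 in fasted rats, and Mmrn1 had 0.09451 for refeeding in control rats. With the extraction run as a block 22 passed for fasting in cafeteria rats. Run 1 holds 1 cafeteria fasted and 1 cafeteria refed array, and run 2 holds 1 control fasted and 1 cafeteria fed array, so most values of a single run rest on lone rats, assumed to vary like the other groups, and settle no direction. In run 1 alone, with 14 arrays, 0 passed for fasting in control, 15 in cafeteria, 538 for refeeding in control, 4 in cafeteria, 1 for refed against fed in cafeteria rats, 0 for the diet in fed, 22 in fasted, 1 in refed rats, 7 averaged and 1 for the interaction with refeeding. In it lists took the other direction for ribosomal proteins (fasting in control, adjusted p = 0.01478, and the diet in fed, 0.009684, range 2.809e-59 to 0.8554), NK markers (refeeding in cafeteria, 0.03187, range 2.045e-05 to 0.8737) and platelet markers (diet in refed, 0.03943, range 9.885e-06 to 0.8692). So did Ahsp (-0.8907) and Gzmb (0.9947) for refeeding and Rhd (-0.261) and Slc4a1 (-0.2787) for refed against fed in cafeteria rats, Slc27a2 (-0.6223) for the diet averaged and Xcl1 (0.4427) for the interaction with refeeding. In run 2 alone, with 15 arrays, 4 passed for fasting in control, 0 in cafeteria, 9 for refeeding in control, 0 in cafeteria rats, 0 for the diet in fed, 4 in fasted, 0 in refed rats, 2 averaged and 1 for each interaction. In it lists took the other direction for T cell markers (diet in fed, adjusted p = 0.003444, range 2.191e-10 to 0.8554), immediate early genes (interaction with fasting, 0.04866, range 1.638e-05 to 0.6303) and plasma cell markers (the same interaction, 0.04866, range 0.01387 to 0.913). So did Ifit1 (-0.1073) and Cpt1a (-0.07078) for fasting in cafeteria rats, Cd3e (0.1053) and Cd72 (-0.01403) for the diet in fed, Mzb1 (0.4151) and Tnfrsf17 (0.9909) for the diet in fasted rats, and Rpgrip1 (0.1263), Il1b (-0.02051) and Cxcl2 (-0.2602) for the interaction with fasting. Of the 107 list calls, 2 held with an estimated correlation and 71 with slide as a block.

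With 1 array left out, fasting in control rats gave 6 to 81 genes (control fed 4 6, 1 7, 7 8, 13 21; control fasted 14 14, 2 15, 8 15, 5 81). Fasting in cafeteria rats gave 10 to 303 (cafeteria fasted 11 10, 5 54, 14 131; cafeteria fed 7 25, 1 34, 13 61), refeeding in control rats 1684 to 2159 and refeeding in cafeteria rats 74 to 520 (cafeteria fasted 11 74, 5 154; cafeteria refed 15 133, 9 156, 3 165, 12 520). The diet gave 0 to 3 in fed rats (0 without cafeteria fed 10, control fed 13 or control fed 7, 3 without cafeteria fed 4), 58 to 365 in fasted rats (control fasted 5 58, 8 64, 2 94; cafeteria fasted 11 65, 5 69, 14 73, 8 77, 2 365), 4 to 139 in refed rats (cafeteria refed 15 4, 9 20, 3 139; control refed 3 4, 6 10, 12 29) and 619 to 894 averaged, where the numbers in parentheses are the rat left out and the genes that passed without it.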

Other observations

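Slc27a2 took widely separate values between rats. Below a log2 ratio of -3, a limit chosen after its values were seen, lay 11 of 29 arrays, from -4.86 to -3.99, and the other arrays lay between -2.04 and 1.61. The arrays below the limit were 3 of 4 control fed, 1 of 5 control fasted, 2 of 5 control refed, 0 of 5 cafeteria fed, 2 of 5 cafeteria fasted and 3 of 5 cafeteria refed arrays. They were 3 of 14 arrays in extraction run 1 and 8 of 15 in run 2. The gene's 2 probes lay on the same side of the limit on 27 of 29 arrays.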
